A study of Mus musculus with 9 samples.

How the data were processed

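The samples are the milk fat of 9 primiparous female ICR mice, a CD1 outbred stock, 1 library per dam, on a control diet (n = 5) or a high fat diet (n = 4). Per the labels' protocols, feeding began at 4 weeks of age and went on through mating, pregnancy and lactation, the diets were matched at 7% of energy from sucrose and held 3.85 and 5.24 kcal per gram, and dams were kept in pairs within a diet before mating. The labels do not tie dams to cages, so dams of one diet are not fully independent if cage mattered. The fat layer was skimmed after centrifugation and spun again in saline to remove trapped cells, total RNA was extracted, and libraries were made with a stranded total RNA kit.

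The authors deposited 1 table per library with FPKM per gene and the lower and upper confidence bounds of FPKM, per the file headers. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, TopHat, Cufflinks, HTSeq and DESeq2, and their versions, the strand setting and the genome build are not given in the sources used here. The bounds and status columns have the form that Cufflinks writes, per the file headers. Counts were not analysed here, so no count test was run. The lowest FPKM in every table was just above 1 and all rows had the status OK, so genes at or below 1 FPKM have no row. Gene identifiers were matched to GENCODE M21 (GRCm38): 11165 of 11206 were found, 41 were not, and 9309 had identical bounds after adding 1 to the start, so coordinates are read as GRCm38.

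For 6 gene identifiers a table repeated the gene, and the highest FPKM was kept. Blank rows, 1 each in control diet 3 and 4, and 26 stray text cells beside the table of control diet 2 were not used. In 14 genes the symbol had been turned into a date, and these genes were named nowhere. A further 17 symbols are shared with another identifier.

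FPKM divides by depth and keeps no total. The bounds lie 2 standard deviations from the FPKM, so the squared ratio of FPKM to its standard deviation estimates the fragments behind a gene. Per unit of FPKM, this number scales with the depth of the library. Over 507 genes with 1 annotated transcript and a row in all 9 libraries, its ratio to control diet 1 ran from 0.823 to 1.59. The median listed gene rested on 20.0 to 41.1 such fragments in the control diet libraries and on 28.6, 13.0, 7.64 and 27.8 in high fat diet libraries 1 to 4, so values near 1 FPKM are least certain in high fat diet 2 and 3.

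Genes with an FPKM of at least 1 in at least 4 libraries were tested, 7983 in all, with unlisted genes set to 0. Limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a mean-variance trend and diet as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fold change on this scale understates the change of genes at low FPKM. For genes unlisted in some library, the listed values are given in place of a mean. Of 40 gene lists fixed beforehand, 33 had at least 3 tested members and were tested with camera at a preset correlation of 0.01. With an estimated correlation, whose median was 0.592, camera called 0 lists, against 10 lower and 3 higher at the preset value. Fry, which asks whether a list moves on balance in 1 direction and does not compare it with other genes, called 15 lists lower. Lists of hormone-sensing luminal, T and NK cell, B and plasma cell, endothelial, fibroblast, erythroid and liver markers had 0 to 2 tested members and were not tested.

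Numbers of listed genes and shares of summed FPKM were compared by exact permutation tests over all arrangements of 9 samples into 5 and 4, 2-sided, with a smallest possible p of 0.00794. Genes were named by a rule: the 10 largest rises and falls among called genes without overlap between the diets, filled by the smallest unadjusted p where fewer passed; for each described list, up to 4 members of smallest p and the most abundant member; the 10 most abundant named genes; and a fixed set of milk protein and lipid genes. Of the fixed set, Cpt1a and Gpam were unlisted in all libraries and Elovl6 was listed in 2.

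The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Alternatives changed the pseudocount, the filter, the scaling of the libraries, library weights, the number of listed genes as a covariate, the variance model, the replicate number as a block, and each library in turn. Added after seeing the data were a floor of 1 for unlisted genes, size factors over genes listed in all 9 libraries, scaling to nuclear protein-coding FPKM, and leaving out high fat diet 2 and 3 together.

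The fit was tested on simulated data for the comparison of high fat with control diet, with 200 genes changed. With libraries on 1 scale and 9382 genes tested, 30% of genes changed by 1 on the log2 scale and 76% of those changed by 2 were recovered, with 13 unchanged genes called. With the libraries on the scale of the real ones and 10167 genes tested, recovery was 3% and 46%, with 35 unchanged genes called, 34 of them lower. After median-of-ratios scaling of the same data it was 14% and 83%, with 10 unchanged genes called, all lower. Noise was drawn for each gene independently, so genes that move together beyond the shared scale of a library were not simulated. More genes passed the filter than the 7983 of the real data, and the changed genes were drawn from widely listed genes. The counts of unchanged genes called are therefore not an error rate for the real comparison. Tables were joined in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.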

Results

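Total RNA of the milk fat layer was sequenced from 9 first-litter ICR mice at lactation day 10. The milk fat layer holds fat globules that carry cytoplasm of the mammary epithelial cells which secreted them, so its RNA is a sample of that epithelium. Of the dams, 5 were fed a control diet with 10% of energy from fat and 4 a high fat diet with 60% of energy from fat, both from 4 weeks before mating onward. The values are FPKM, a fragment count scaled to transcript length and library size, per gene and library, and the tables hold rows only for genes with an FPKM above 1. A gene with no row in a library is called unlisted and was counted as 0 in the tests. In all, 11206 genes were listed in at least 1 library and 1847 in all 9. Relative depth was read from the confidence bounds of 507 genes with 1 annotated transcript, with control diet 1 set to 1. It was 1.00, 1.08, 1.12, 1.21 and 1.19 in control diet libraries 1 to 5, and 1.21, 0.823, 0.930 and 1.59 in high fat diet libraries 1 to 4.

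The first comparison asked how many genes could be seen in the milk fat RNA of each diet. High fat diet libraries listed fewer genes than control diet libraries, 5040 ± 2409 (SD, n = 4) against 8386 ± 735 (SD, n = 5; exact permutation test, 2-sided, p = 0.0159, adjusted p = 0.0238 over 3 thresholds). The thresholds of above 0 and at least 1 FPKM gave the same counts, as the tables start above 1. The family of 3 thus repeats a test, which makes this adjusted p smaller than over distinct tests. Genes at an FPKM of at least 10 numbered 835 ± 495 (SD, n = 4) against 1690 ± 469 (SD, n = 5; exact permutation test, p = 0.0317). The control diet libraries listed 8487, 7098, 8903, 8695 and 8746 genes. High fat diet library 1, with 7974 genes, lay inside the control range, while libraries 2, 3 and 4 listed 5124, 2075 and 4986. The 57 nuclear-encoded oxidative phosphorylation genes, which supply the respiratory chain, were all listed in each control diet library and 51 of them were still listed in high fat diet 3. Of 29 cell cycle genes listed anywhere, 13 to 28 were listed in the control diet libraries, 15 in high fat diet 1, 5 in high fat diet 2, 0 in high fat diet 3 and 1 in high fat diet 4. Leaving out any 1 of control diet 1, 3, 4 and 5 or high fat diet 2, 3 and 4 ended the call on listed genes, with adjusted p between 0.0536 and 0.0571, and that at 10 FPKM, with adjusted p between 0.0536 and 0.0893 (exact permutation tests).

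**Figure D1:**
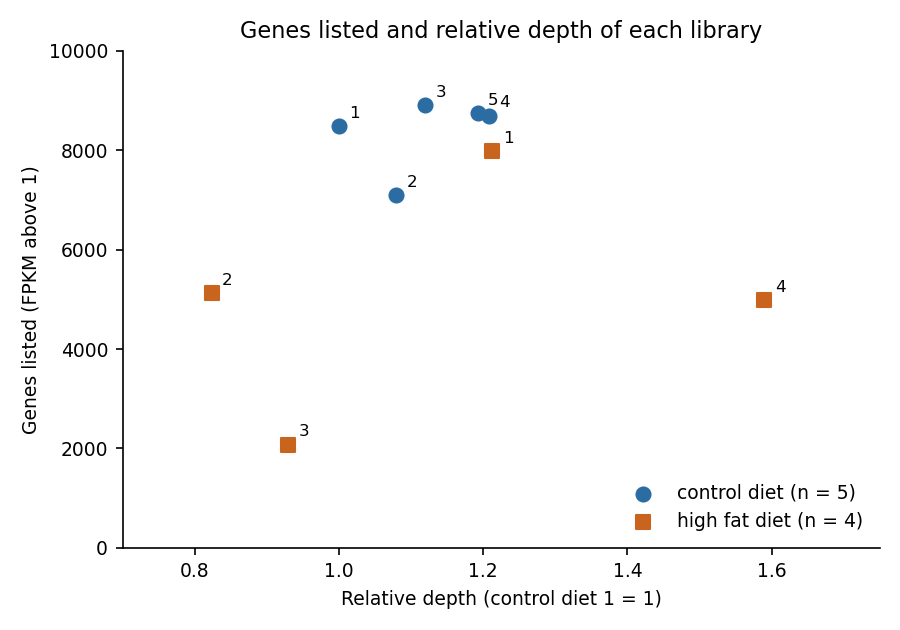
Genes listed in each library (vertical axis, genes with an FPKM above 1) against the relative depth of the library (horizontal axis, control diet 1 set to 1), with the replicate number beside each point. High fat diet 4, the deepest library at 1.59, listed 4986 genes, fewer than every control diet library.

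The second comparison asked which transcripts differed between the diets. On the high fat diet, the heat shock and ER stress gene lists were lower than other genes in milk fat (camera adjusted p = 6.37e-08 and 7.6e-08, adjusted p = 0.905 and 0.977 with an estimated correlation). Single transcripts such as Saa2, Hmox1 and Cldn4 fell, while the most abundant milk protein and fat globule transcripts did not pass the test. Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, was listed in all 5 control diet libraries at 8.03 to 45.4 FPKM and in 1 high fat diet library at 5.65 (log2 fold change -3.49, SE 0.629, limma adjusted p = 0.000618). Saa2, an acute-phase serum amyloid A, was at 173 to 898 FPKM on the control diet and at 32.4 to 105 in the 3 high fat diet libraries that listed it (log2 fold change -4.08, adjusted p = 0.0102). Scd1, the desaturase that makes oleic from stearic acid, fell from 128 ± 38.1 FPKM (SD, n = 5) to 32.0 ± 30.3 (SD, n = 4; log2 fold change -2.58, SE 0.843, limma adjusted p = 0.0333). Limma on log2(FPKM + 1) called 1662 of 7983 genes lower on the high fat diet and 0 higher, with 3952 lower and 5 higher at an unadjusted p under 0.05. Of the lower genes, 1480 were protein coding. The median log2 fold change of all tested genes was -1.08, a ratio of 0.474, so each fold change below is read against that shift. The diets did not overlap in 884 genes, 11.1% of those tested, and in all 884 the control diet values were the higher. By chance 1.59% is expected for either direction in a gene taken alone. Genes share the scale of their library and can separate together, so this comparison does not weigh chance. After scaling the libraries by median-of-ratios size factors, limma called 0 genes, with 53 higher and 1600 lower at an unadjusted p under 0.05 and a median of -0.55. As deposited, without control diet 1, 3, 4 or 5 the count of lower genes was 808, 82, 290 or 259, and without high fat diet 1, 2, 3 or 4 it was 5215, 74, 16 or 162, while higher genes numbered 0 to 4.

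The 10 largest falls without overlap between the diets were led by 4 copies of the small nucleolar RNA gene Rnu3b, at 186 ± 49.4 FPKM on the control diet for Rnu3b1 (SD, n = 5) and 5.34 to 36.5 in the 3 high fat diet libraries that listed it. Each of these copies shares its position on chromosome 11 with another gene identifier of the same name, which was listed in 1 control diet and 3 high fat diet libraries, so fragments were split between the identifiers and the fall is uncertain. The others were Saa2, Saa1, Hmox1, Orm2, Hspa1b and Hspa1a, with log2 fold changes between -4.08 and -2.95. Saa1 and Saa2 are near-identical neighbours on chromosome 7, and Hspa1a and Hspa1b, which encode the inducible heat shock protein Hsp70, are near-identical neighbours on chromosome 17, so the division of fragments within each pair is uncertain, as it is between Orm2 and its near-identical relatives. No gene passed as higher. Among genes with a name and a positive log2 fold change, predicted Gm genes left out, the unadjusted p was smallest for the other Rnu3b identifiers, the pseudogene RP23-146N20.3, Cav2, Pfas, Cnbd2, Inpp1 and Timm10b, the last 6 at limma adjusted p between 0.142 and 0.210. Several were higher on the log2(FPKM + 1) scale but lower in mean FPKM, as 1 or 2 control diet libraries held high values. RP23-146N20.3 was at 799 and 487 FPKM in 2 control diet libraries and at 116 to 484 in 3 high fat diet libraries, Cav2 at 33.4 in 1 control diet library and at 2.57 to 7.98 in 3 high fat diet libraries, and the other Rnu3b identifiers at 197 to 198 in control diet 5 alone and at 1.12 to 124 in 3 high fat diet libraries. Of the predicted genes, Gm14435, chosen after its values were seen, had an unadjusted p of 0.0443 (limma adjusted p = 0.0952) and was listed in 1 control diet and 3 high fat diet libraries. Cnbd2 was at 536 FPKM in high fat diet 4 and at 70.6 in control diet 2, and between 0 and 11.8 in the other libraries.

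**Figure D2:**
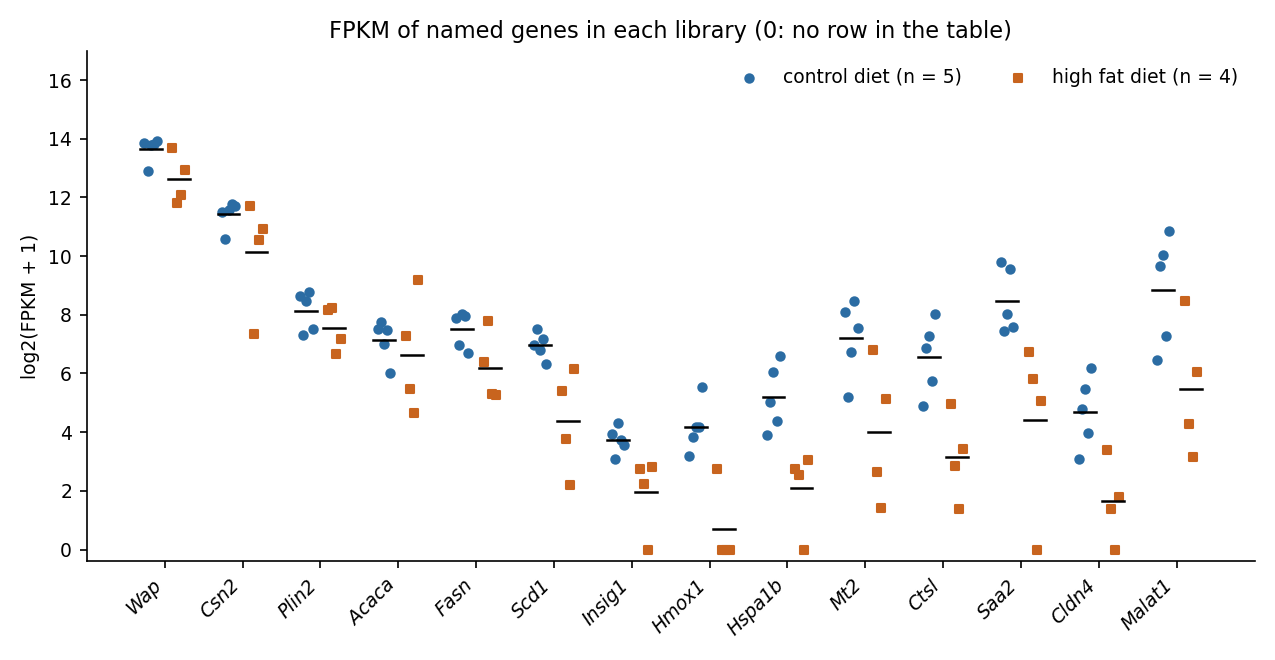
FPKM of 14 named genes in each library, as log2(FPKM + 1), with points for single libraries (control diet n = 5, high fat diet n = 4), black lines for group means, and 0 for a library with no row for the gene. Scd1 and Hmox1 show no overlap between the diets, while Wap, Plin2 and Acaca overlap and turned positive after median-of-ratios scaling.

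Among fat synthesis genes, 5 of 21 members of de novo fatty acid synthesis fell and 16 did not pass (6 fell when adjusted over the list alone). Besides Scd1 these included Insig1, a brake on sterol-regulated transcription, at 12.8 ± 4.27 FPKM on the control diet (SD, n = 5) and at 5.72, 3.66 and 6.0 in 3 of 4 high fat diet libraries (log2 fold change -1.79, limma adjusted p = 0.0426). Idh1 and Mid1ip1 were each listed in all control diet libraries and, of the high fat diet libraries, in high fat diet 1 alone. Relative to the median of all genes, Scd1 and Insig1 lay at -1.50 and -0.71, and Idh1 and Mid1ip1 at -0.36 and -0.14, nearer the shift. Fasn, the fatty acid synthase, was at 195 ± 75 FPKM (SD, n = 5) against 94.9 ± 86.7 (SD, n = 4). Acly was at 222 ± 122 against 90.0 ± 77.6. Neither passed (limma adjusted p = 0.182 and 0.143), and the fold change of Fasn was negative except under quantile normalization. Acaca was at 585 FPKM in high fat diet 4, against 23.9 to 153 in the other high fat diet libraries and 63.2 to 217 on the control diet. Srebf1 and Thrsp had adjusted p of 0.264 and 0.283, and the fold changes of Acaca, Srebf1 and Thrsp were negative as deposited and positive after median-of-ratios scaling. As a group these 21 genes did not differ from other genes (camera adjusted p = 0.209). Cholesterol synthesis was lower than other genes, with 7 of 18 members called and 14 when adjusted over the list alone (camera adjusted p = 0.0106, adjusted p = 0.989 with an estimated correlation). The call ended after scaling to 1 sum (camera adjusted p = 0.0994) but held after median-of-ratios scaling (camera adjusted p = 0.0241, adjusted p = 0.752 with an estimated correlation). Cyp51, at 1.38 to 5.55 FPKM, and Sqle, at 1.34 to 3.47 FPKM, were listed in all 5 control diet libraries and in 0 high fat diet libraries.

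The fat globule and milk protein groups were not called against other genes as deposited. Of 18 fat globule and secretion genes, 1 was called lower, and 0 when adjusted over the list alone (camera adjusted p = 0.668). After median-of-ratios scaling the list was higher than other genes (camera adjusted p = 1.43e-05, adjusted p = 0.135 with an estimated correlation). The called gene was Dgat1, a triglyceride synthesis enzyme, listed in 5 control diet libraries and 1 high fat diet library. Its log2 fold change lay at -0.35 relative to the median of all genes. Plin2, the lipid droplet coat protein, was at 306 ± 127 FPKM (SD, n = 5) against 207 ± 99.9 (SD, n = 4; limma adjusted p = 0.535), and Btn1a1 and Xdh, which anchor the globule membrane, had adjusted p of 0.273 and 0.405. The fold changes of Plin2, Btn1a1, Xdh, Cd36 and Lpl were negative as deposited and positive after median-of-ratios, quantile and protein-coding scaling. Of 20 milk protein genes, 3 fell: Spp1, Lpo and Lcn2, with 3 when adjusted over the list alone. Relative to the median of all genes, Spp1 and Lcn2 lay at -1.66 and -1.43, but Lpo only at -0.18, close to the shift. Spp1, which encodes osteopontin, was at 193 ± 150 FPKM (SD, n = 5) against 42.2 ± 46.4 (SD, n = 4; log2 fold change -2.74, limma adjusted p = 0.0322). Lcn2, the iron-scavenging lipocalin, was at 391 ± 186 against 116 ± 137 (limma adjusted p = 0.0436). The caseins Csn2 and Csn1s2b, whey acidic protein Wap and alpha-lactalbumin Lalba did not pass (adjusted p = 0.206, 0.487, 0.244 and 0.342). Wap was at 13352 ± 3231 FPKM on the control diet (SD, n = 5) and at 7227 ± 4408 on the high fat diet (SD, n = 4), and the fold changes of Wap, Lalba and Csn1s2b, negative as deposited, were positive after median-of-ratios scaling. Milk proteins did not differ from other genes as deposited (camera adjusted p = 0.831), and were higher than other genes after median-of-ratios scaling (camera adjusted p = 0.0113, adjusted p = 0.752 with an estimated correlation). Over genes listed in all 9 libraries with size factors, the 18 milk protein members did not differ from other genes (camera adjusted p = 0.522). There the 14 fat globule members were still higher (camera adjusted p = 0.0283, adjusted p = 0.558 with an estimated correlation).

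Fatty acid oxidation and PPAR target genes were lowered less than other genes, with a median 0.30 above that of all genes on the log2 scale, negative as deposited and positive under quantile normalization. Of the 26 members, 2 were called lower, Ppard and Acadl (camera adjusted p = 0.00239, adjusted p = 0.989 with an estimated correlation, 0 adjusted over the list alone). Relative to the median of all genes these 2 lay at -0.38 and -0.35. Pdk4 and Angptl4, targets of PPAR receptors, had limma adjusted p of 0.178 and 0.104. Ucp2, the most abundant member, did not pass (adjusted p = 0.175). Cytosolic ribosomal proteins were also lowered less, with 1 of 71 members, Rpl35a, called lower and 1 when adjusted over the list alone. Their median log2 fold change lay 0.14 above that of all genes, negative as deposited and positive after median-of-ratios and quantile scaling (camera adjusted p = 0.0006, adjusted p = 0.989 with an estimated correlation).

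Of 17 heat shock genes, 11 were lower, and 14 when adjusted over the list alone (camera adjusted p = 6.37e-08, adjusted p = 0.905 with an estimated correlation). Hspb1, a small heat shock protein, was at 4.82 to 27.9 FPKM in the control diet libraries and at 2.13 and 1.11 in the 2 high fat diet libraries that listed it (log2 fold change -2.87, limma adjusted p = 0.00295). Dnajb1, a co-chaperone, was lower too (adjusted p = 0.00801). Of 24 ER stress and unfolded protein response genes, 18 were lower, and 21 when adjusted over the list alone (camera adjusted p = 7.6e-08, adjusted p = 0.977 with an estimated correlation). Hspa5, the ER chaperone BiP, was at 58.9 ± 49.2 FPKM (SD, n = 5) against 7.72 ± 3.23 (SD, n = 4; log2 fold change -2.39, limma adjusted p = 0.0314). Ddit3, a stress transcription factor, was at 3.60 to 24.9 FPKM in the control diet libraries and at 4.11 and 1.26 in 2 high fat diet libraries. Pdia4 was listed in 5 control and 0 high fat diet libraries. Of 21 oxidative stress genes regulated by Nrf2, 9 were lower, and 12 when adjusted over the list alone (camera adjusted p = 0.0035, adjusted p = 0.989 with an estimated correlation). The metallothionein Mt2 was at 36.0 to 353 FPKM on the control diet and at 1.66 to 109.5 on the high fat diet (log2 fold change -3.21, limma adjusted p = 0.0203). The ferritin chain Fth1 did not pass (3948 ± 1216 against 1368 ± 1081, adjusted p = 0.0809). Of 20 immediate early genes, 14 were lower, among them Myc, Klf6 and Atf3 (limma adjusted p = 0.0161, 0.0161 and 0.0199), with 17 when adjusted over the list alone (camera adjusted p = 0.000254, adjusted p = 0.989 with an estimated correlation). The log2 fold change of every gene named in this paragraph was negative under each of the scalings tried. After median-of-ratios scaling the heat shock, ER stress, Nrf2 and immediate early lists were still lower than other genes (camera adjusted p = 0.00151, 0.0038, 0.0319 and 0.0109, adjusted p between 0.752 and 0.920 with an estimated correlation). Over genes listed in all 9 libraries with size factors, the 10 Nrf2 members were still lower (camera adjusted p = 0.000741, adjusted p = 0.558 with an estimated correlation). There the heat shock and ER stress calls ended on 4 and 7 members (camera adjusted p = 0.0708 and 0.0918), with medians of -0.58 and -0.45. Heat shock, ER stress and immediate early genes listed in all 9 libraries numbered 13, without the Nrf2 list. Their scaled levels in control diet 1 and 4, -0.64 and -0.28, lay within the high fat diet range of -0.67 to 0.00. Those of control diet 2, 3 and 5, 0.70, 0.32 and 1.18, lay above it. For the 10 Nrf2 members, control diet 1, 2, 4 and 5, at 0.27, 0.13, 0.49 and 0.64, lay above the high fat diet range of -0.85 to 0.07. Control diet 3, at 0.04, lay within it.

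Epithelial and involution genes were lower too. Of 18 markers of luminal secretory epithelium, 8 were lower, and 11 when adjusted over the list alone (camera adjusted p = 0.00165, adjusted p = 0.989 with an estimated correlation). These were led by the tight junction proteins Cldn4, at 7.51 to 72.6 FPKM on the control diet and at 1.60 to 9.50 in 3 high fat diet libraries (log2 fold change -3.06, limma adjusted p = 0.00865), and Cldn3, with the adhesion protein Epcam (adjusted p = 0.011 and 0.0181). The lactogenic transcription factor Elf5 did not pass (172 ± 98.1 against 80.3 ± 57.1 FPKM, adjusted p = 0.216) and turned positive after median-of-ratios scaling. Of 17 genes of mammary involution, the regression of the gland after weaning, 9 were lower and 13 when adjusted over the list alone (camera adjusted p = 0.000254, adjusted p = 0.989 with an estimated correlation). They included the lysosomal proteases Ctsl, at 122 ± 91.8 FPKM (SD, n = 5) against 11.9 ± 12.6 (SD, n = 4; log2 fold change -3.41, limma adjusted p = 0.0115), and Ctsb (adjusted p = 0.014), and the galectin Lgals3 (adjusted p = 0.0161). After median-of-ratios scaling the luminal and involution calls ended (camera adjusted p = 0.576 and 0.0814), with medians 0.26 and 0.45 below that of all genes, against 0.47 and 0.53 as deposited. Over genes listed in all 9 libraries with size factors, the 7 involution members were lower than other genes (camera adjusted p = 0.00359, adjusted p = 0.558 with an estimated correlation) and the 9 luminal ones were not (camera adjusted p = 0.125). The 3 tested keratinocyte markers were all lower, and 3 when adjusted over the list alone (camera adjusted p = 0.000215, adjusted p = 0.521 with an estimated correlation). Of 8 keratinocyte markers listed anywhere, however, high fat diet 1 listed 7, the control diet libraries 3 or 4 and the other high fat diet libraries 0 to 2. With no filter on low values the keratinocyte list lay 1.00 above other genes (camera adjusted p = 0.00292, adjusted p = 0.946 with an estimated correlation), but 5 of its 12 members were then identifiers of 1 gene, Flg, each listed in high fat diet 1 alone.

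Among 12 tested nuclear and small structural RNAs, 5 were lower, and 5 when adjusted over the list alone (camera adjusted p = 0.287). They included the nuclear-retained long RNA Malat1, at 787 ± 718 FPKM (SD, n = 5) against 111 ± 162 (SD, n = 4; log2 fold change -3.38, limma adjusted p = 0.0234). Neat1 and Xist, also nuclear-retained, were lower as well (adjusted p = 0.0161 and 0.025). The small cytoplasmic RNA Rn7s6, the most abundant named gene, was at 164960 ± 58055 FPKM (SD, n = 5) against 166320 ± 74346 (SD, n = 4; limma adjusted p = 0.966), with a positive fold change after median-of-ratios scaling. Mitochondrially encoded genes had a median log2 fold change of -2.11, with 2 of 13 lower and 7 when adjusted over the list alone (camera adjusted p = 7.71e-05, adjusted p = 0.989 with an estimated correlation). This call ended after median-of-ratios scaling (camera adjusted p = 0.712) and held over genes listed in all 9 libraries with size factors (median -0.85, camera adjusted p = 0.0283, adjusted p = 0.623 with an estimated correlation). Compared by library, the scaled level of these 13 genes did not pass (difference -0.80, exact permutation test, p = 0.5). It was lowest in high fat diet 2, at -3.38, and highest in high fat diet 3, at 1.90. mt-Co1 was at 160 FPKM in high fat diet 2, against 606 to 1240 in the other high fat diet libraries and 1227 to 3005 on the control diet. Replication-dependent histones were lower than other genes, with 11 of 30 called and 17 when adjusted over the list alone (camera adjusted p = 0.00395, adjusted p = 0.989 with an estimated correlation), a call that ended after median-of-ratios scaling (camera adjusted p = 0.339). Over genes listed in all 9 libraries with size factors, 16 histones were lower than other genes (camera adjusted p = 0.0283, adjusted p = 0.558 with an estimated correlation). Of 21 housekeeping genes, 2 were called, and 0 when adjusted over the list alone (camera adjusted p = 0.09, adjusted p = 0.989 with an estimated correlation). After median-of-ratios scaling the list did not differ from other genes (camera adjusted p = 0.694). Over genes listed in all 9 libraries with size factors, however, 17 housekeeping genes were lower than other genes (median -0.32, camera adjusted p = 0.0218, adjusted p = 0.558 with an estimated correlation). Gapdh was at 26.6 ± 13.1 against 8.88 ± 10.4 FPKM (adjusted p = 0.0519) and Eef1a1 at 538 ± 249 against 347 ± 243 (adjusted p = 0.351), and the fold change of Eef1a1, unlike that of Gapdh, turned positive after median-of-ratios scaling. The 8 tested macrophage markers had a median log2 fold change of -0.31, positive under every other scaling tried, with 0 called over all genes and 0 when adjusted over the list alone (camera adjusted p = 3.49e-06, adjusted p = 0.521 with an estimated correlation). Of 17 such markers listed anywhere, control diet 1 to 5 listed 11, 4, 7, 12 and 3, and high fat diet 1 to 4 listed 11, 5, 10 and 1. Markers near the floor, such as C1qa, at 5.28, 0, 2.07, 2.11 and 0 FPKM in control diet 1 to 5, have little room to fall with other genes. The position of this list above other genes may therefore come from its low values. Neutrophil markers were listed mostly in high fat diet 1, at 15 of 16 against 2 to 8 in the other libraries.

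**Figure D3:**
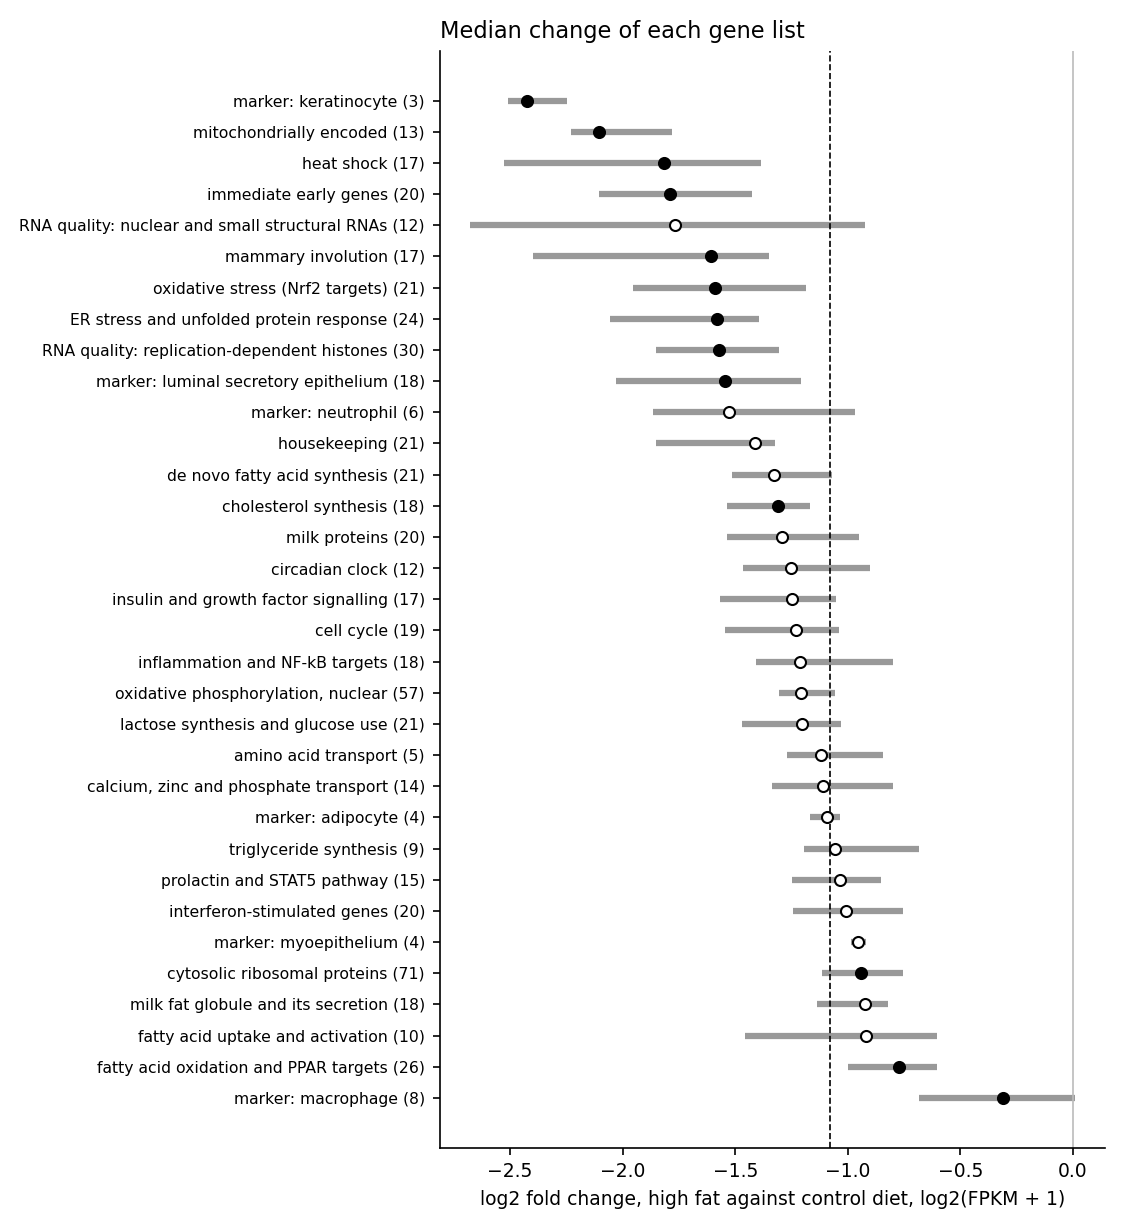
Median log2 fold change of each tested gene list, high fat against control diet on log2(FPKM + 1), with the number of tested members in parentheses and grey bars for the middle 50% of members. Filled points passed camera at its preset correlation, open points did not, the dashed line is the median of all tested genes, -1.08, and the ribosomal, fat globule and macrophage medians turned positive after median-of-ratios scaling.

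Genes listed in every library of one diet and no library of the other numbered 123 for the control diet and 0 for the high fat diet. They included the sterol enzymes Cyp51 and Sqle, the ER chaperone Pdia4, and Lgmn, a lysosomal protease chosen after its values were seen, at 1.04 to 8.91 FPKM. All had control diet means under 5 FPKM, and none was listed at 10 FPKM or more in every control diet library. Without control diet 1 or 2 the count was 225 or 275, and without high fat diet 1 it was 851.

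The last comparison asked how the summed FPKM was divided. FPKM divides by transcript length, so shares of its sum are not shares of fragments. Protein-coding genes held 2.19% to 4.94% of summed FPKM, while nuclear protein-coding genes held 18.7% to 68.0% of the fragments estimated from the bounds. The most abundant gene of a library was Gm24270, Gm24245 or Gm23935, with 23.5% to 43.4% of the sum. The 10 most abundant genes of each library held 92.6% ± 2.69 on the control diet (SD, n = 5) and 95.5% ± 0.971 on the high fat diet (SD, n = 4; exact permutation test, p = 0.0714, adjusted p = 0.286 over 4 shares). Milk proteins held 1.21% ± 0.393 (SD, n = 5) against 1.02% ± 0.442 (SD, n = 4; exact permutation test, adjusted p = 0.508), and the difference of -0.191 points was 0.0287 without high fat diet 2. Mitochondrially encoded genes held 0.260% ± 0.113 (SD, n = 5) against 0.138% ± 0.136 (SD, n = 4; exact permutation test, adjusted p = 0.381). Cytosolic ribosomal proteins held 0.114% ± 0.0396 (SD, n = 5) against 0.0847% ± 0.0419 (SD, n = 4; exact permutation test, adjusted p = 0.402). None of these 4 differences passed the test.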

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

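Apart from the counts of splits, the tests of explanations in this part were chosen after the results were seen. In 203 groups of libraries, taken over the 97 genes named in the text and 10 library measures, 38 had 1 library far from the others of its diet, against 10.15 expected by chance. Some of these genes were named because of such values. A gene listed in 1 library of its diet also passes by construction, as its other values are all 0. Both raise the count, and the 10.15 allows for neither. High fat diet 1 was the only library of its diet to list Hmox1 (5.65 FPKM), Idh1 (2.71), Mid1ip1 (1.36), Dgat1 (2.20), Ppard (2.30), Acadl (3.95), Srxn1 (3.02), Myc (3.20), Cdk1 (5.00), Gata3 (2.26), Nfil3 (1.94), Nr1d1 (1.96), Socs2 (2.22) and Flg (7.48 summed over its identifiers). The same held for the neutrophil and chemokine genes Il1b (24.3), S100a8 (40.9), S100a9 (48.3), Cxcl2 (52.9) and Ccl3 (34.1). Lpo was likewise listed in high fat diet 2 alone among its diet, at 1.27 FPKM, and Igkc and Ighm in high fat diet 3 alone, at 3.25 and 2.69. Saa1, Hspa1b, Hspa1a and Pfas were at 0 in high fat diet 3 and listed in the other 3 libraries of that diet. Among control diet libraries, Cav2 was listed in control diet 1 alone, at 33.4 FPKM, Pfas and Lyz2 in control diet 4 alone, at 1.27 and 1.30, and Gm14435 in control diet 3 alone, at 4.97, while S100a9 was at 0 in control diet 4 alone. Control diet 2 was lowest for Csn1s2b (6552 FPKM), Csn2 (1534) and Wap (7636) and for listed genes (7098), and control diet 5 was highest for Dgat1 (4.73) and Per1 (10.9). Milk proteins held 0.366% of summed FPKM in high fat diet 2, the lowest share.

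The lower FPKM and fewer listed genes of the high fat libraries are a pattern of most genes, so technical explanations come first. Fewer fragments were not seen on average: the mean relative depth of the high fat libraries was 1.02 times that of the controls. A drop in depth as large as the median FPKM ratio of 0.474 was rejected (exact permutation test, p = 0.00794, the smallest possible). FPKM divides by depth, so this test bears on depth and not on FPKM itself. Depth may still limit which genes were listed in high fat diet 2 and 3, at 0.823 and 0.930. High fat diet 4, at 1.59, nevertheless listed fewer genes than every control diet library. Structural and mitochondrial RNA taking up fragments cannot be told apart from the diet, because the protein-coding share of implied fragments, 0.929 times that of the controls, varied between 18.7% and 68.0% on the high fat diet (exact permutation test against a drop of that size, p = 0.0714). A larger share of fragments outside the listed genes also cannot be told apart, since fragments in listed genes per unit of depth, 0.473 times those of the controls, follow from the FPKM themselves. Whether such a share would be technical or biological stays open.

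Chance was weighed by regrouping the 9 libraries into 5 and 4, with 100 splits drawn, the real one included. Of these, 3, the real one among them, called at least as many genes as the real 1662, with 5840 the highest other. The count of genes thus passed at the 0.05 level over the splits drawn, but not every possible split was drawn. Other groupings also called more genes than the diets did, so the count alone does not exclude chance. The split with 5840 set control diet 2 with high fat diet 2, 3 and 4 against the rest, high fat diet 1 included. The next, with 2606, set control diet 1, 3 and 4 and high fat diet 1 against the rest. The libraries thus have a structure that follows the diet only in part. For gene lists, 31 splits called at least the real 13, with 17 the highest other, so chance is not excluded for the number of lists. For genes listed in every library of one diet and in none of the other, 4 splits gave at least the real 123, with 311 the highest other.

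The heat shock, ER stress, Nrf2 and immediate early lists were lower than other genes beyond the shift, at adjusted p between 0.905 and 0.989 with an estimated correlation. Counting unlisted genes as 0 can exaggerate this. Over the 13 heat shock, ER stress and immediate early genes listed in all 9 libraries, scaled to the library, the difference was -0.58 on the log2 scale (exact permutation test, p = 0.183). The Nrf2 list was not pooled into these 13. Over its 10 members listed in all 9 libraries the difference was -0.70 (exact permutation test, p = 0.0159, adjusted p = 0.365 over 23 lists). These values leave that explanation open. Less nuclear RNA in the high fat milk fat, from fewer shed cells or nuclei, is a candidate explanation, since the median of Malat1, Neat1 and Xist lay at -1.79 relative to all genes. Within diets, scaled Malat1 followed the 13 heat shock, ER stress and immediate early genes with Pearson r = 0.847 (exact permutation test, n = 9, p = 0.0194). Spearman rho was 0.783 (exact permutation test, p = 0.0535). This was the only relation computed, and it left out the Nrf2 list. Without control diet 1 and 4, r was 0.650 (exact permutation test, n = 7, p = 0.139), which did not pass with 7 libraries, and fewer nuclei and a diet effect on stress genes cannot be told apart.

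High fat diet 1 held neutrophil genes. Of 16 listed markers, 15 were listed there, and 12 of the 16, or 75%, had their highest FPKM in that library, among them S100a9 (48.3 FPKM), S100a8 (40.9) and Il1b (24.3, listed in no other library). A broader library does not account for it, since the 4 libraries that listed more genes listed at most 8 of these markers. Neutrophils carried in the fat layer may be the source, despite the wash step meant to remove cells; the list was fixed beforehand, 1 marker, Ltf, is also a milk protein and 1, Il1b, is also in the inflammation list, and 5 to 8 were listed in each control diet library. No biological cause in the design was tested, as it is 1 library.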

How the results depend on the processing

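Alternatives that set a floor of 1, combine size factors with genes listed in all 9 libraries, scale to protein-coding FPKM or leave out high fat diet 2 and 3 together were chosen after seeing the data. Lower genes numbered 1662 as reported. The count was 145 and 0 with pseudocounts of 0.1 and 10, 13 with no filter (more genes tested). It was 5 at a mean of at least 10 FPKM and 15 over genes listed in all 9 libraries (fewer genes tested), 0 with median-of-ratios size factors, with or without the restriction to genes listed in all 9. It was 0 with quantile normalization, 0 with protein-coding scaling, 6714 with library weights, 0 with listed genes as a covariate, 11 without the trend, 87 with the floor of 1, and 0 without high fat diet 2 and 3 (fewer samples). Leaving out 1 library gave 16 to 5215. Higher genes numbered 0 as reported, 13 with library weights and 0 to 4 leaving out 1 library. Scaling to 1 sum, with or without milk protein and mitochondrial genes, gave 1276 and 1323 lower genes, and the robust variance model 1821. Where no smaller or larger set of genes or samples is named, the cause was not tested.

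Lists lower and higher than other genes by camera, 10 and 3 as reported, were 6 and 6 at a pseudocount of 0.1, 5 and 0 at a mean of at least 10 FPKM, and 6 lower over genes listed in all 9. They were 5 lower with size factors as well, 5 and 1 with library weights, and 7 higher with size factors alone and with protein-coding scaling. Leaving out 1 library gave 9 to 13 and 2 to 4. With an estimated correlation camera called 0 lists under every alternative. The direction against other genes turned from lower to higher for keratinocyte markers, called lower as reported (1.00 with no filter). It also turned for lists not called as reported: neutrophil markers with no filter (1.24), milk proteins with size factors (0.50) and protein-coding scaling (0.38), and nuclear RNAs with library weights (-0.18, the median). For mitochondrially encoded genes with size factors the call was lost (-0.29, camera adjusted p = 0.712). Slc7a7 was at 0.10 under quantile normalization.

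The difference in listed genes stayed negative, between -4324 and -2358 leaving out 1 library, and between -1063 and -670 at FPKM 10. Genes listed in all control and no high fat libraries numbered 0 at FPKM 10 and 1.3e+02 to 851 leaving out 1 library. No share of FPKM passed under any alternative, and thresholds up to 1 changed nothing, as the tables start there.

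With the replicate number as a block over replicates 1 to 4, 38 genes were lower and 4 higher, 16 lists lower and 1 higher, and nuclear oxidative phosphorylation turned lower (-0.29). Libraries with the same number deviated with correlations of 0.14, -0.28, 0.04 and -0.09, and 1 of 4 matched its own number best, so the numbers do not pair the dams. Depth limits values near 1 FPKM most in high fat diet 2 and 3.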

Other observations

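Of the tests in this part, only those over genes listed in all 9 libraries with size factors were chosen after the data were seen. Single genes picked by their values are named as such. Circadian and signalling genes were among those lower on the high fat diet. Of 12 circadian clock genes, 5 were lower, and 7 when adjusted over the list alone (camera adjusted p = 0.375), among them Nfil3, Per1, Nr1d1 and Rora, at limma adjusted p between 0.0201 and 0.0432. Of 17 insulin and growth factor signalling genes, 7 were lower, and 9 when adjusted over the list alone (camera adjusted p = 0.197), among them Irs2, an insulin receptor substrate, at limma adjusted p = 0.0258. Tsc22d3, a glucocorticoid target, was at 19.5 ± 13.3 FPKM (SD, n = 5) against 3.17 ± 1.65 (SD, n = 4; limma adjusted p = 0.0264). Of 14 calcium, zinc and phosphate transport genes, 4 were lower, and 5 when adjusted over the list alone (camera adjusted p = 0.899), led by the phosphate carrier Slc20a1 (limma adjusted p = 0.0161). Of 15 prolactin and STAT5 genes, 2 were lower, Gata3 and Socs2, and 2 when adjusted over the list alone (camera adjusted p = 0.899). Of 19 cell cycle genes, 10 were lower, and 15 when adjusted over the list alone (camera adjusted p = 0.0864), Cdk1 and Mcm3 among them.

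The inflammation and interferon lists did not differ from other genes (camera adjusted p = 0.925 and 0.236), with 7 of 18 and 3 of 20 members lower, and 8 and 0 when adjusted over the list alone. Triglyceride synthesis had 2 of 9 members lower (camera adjusted p = 0.976), fatty acid uptake 0 of 10 (0.249), lactose synthesis and glucose use 1 of 21 (0.375), nuclear oxidative phosphorylation 1 of 57 (0.668), and amino acid transport 2 of 5 (0.842). Adjusted over the list alone these counts were 2, 0, 1, 0 and 2. After median-of-ratios scaling, oxidative phosphorylation and fatty acid uptake were higher than other genes and the cell cycle list was lower (camera adjusted p = 3.43e-06, 0.0241 and 0.00058, adjusted p = 0.752, 0.619 and 0.619 with an estimated correlation). Over genes listed in all 9 libraries with size factors, the 51 oxidative phosphorylation and 5 fatty acid uptake members did not differ from other genes (camera adjusted p = 0.771 and 0.522). Of the adipocyte and myoepithelial markers, 4 tested in each list, 0 were called (camera adjusted p = 0.879 and 0.925). The 6 tested neutrophil markers had 1 called, Slpi, and 4 when adjusted over the list alone (camera adjusted p = 0.976).

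High fat diet 3, which listed the fewest genes, had Lyz2 at 22.4 FPKM, against 1.79 or less elsewhere, and Cd74 at 9.91, against 6.77 in control diet 1, 5.62 in control diet 4 and less elsewhere. It was alone in listing the immunoglobulin genes Igkc and Ighm, at 3.25 and 2.69. The chemokines Cxcl2 and Ccl3 reached 52.9 and 34.1 FPKM in high fat diet 1, against at most 3.75 and 4.44 in the other libraries. These genes were picked after their values were seen.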
